A study of Saccharomyces cerevisiae with 19 samples.

How the data were processed

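The values are intensities of one-colour Agilent arrays. Per the file headers, the deposited raw files came from Agilent Feature Extraction 11.5.1.1, which the submitters' processing notes also name, and gProcessedSignal is the green intensity after the authors' background correction. The deposited flags (well above background, saturated, outlier) came from the same program and were used as given. Per the values, the deposited value table holds log2 intensities shifted to the 75th percentile with no gene centring: its correlation with the values used here was 0.95 to 1.00 for each array. It served only as an alternative. Hybridization and wash conditions beyond the labels are not given in the sources.

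Each array had 13048 spots, 12512 of them not controls, with 2 spots per probe and 6256 probes for 6225 genes. The signal was taken as log2 after dropping outlier spots, the 75th percentile over all non-control spots of the array was subtracted, and the spots of a probe were averaged. For the 29 genes with several probes the brightest was kept. Genes had to be well above background on at least 2 arrays, which removed 58 and left 6167, and 206 gene-array values were missing. Symbols came from the supplied annotation table for 5720 genes, 508 probes had no locus in that table, and 5638 of 5646 probe genes with coordinates in both sources had identical ones.

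A limma group-means model over the 19 arrays (residual degrees of freedom 9, prior degrees of freedom 3.8) gave 14 comparisons: the mean DTT change over 5 strains, the DTT change in each strain, each untreated mutant against WT, and each mutant's DTT change minus that of WT. The 1 WT DTT array was assumed to vary like the other groups. Genes were called at Benjamini-Hochberg adjusted p below 0.05. Camera with a correlation of 0.01 and with an estimated correlation tested 31 lists of at least 3 genes in each comparison, adjusted over the lists. The lists were upr_er_folding, erad, glycosylation_translocation, er_golgi_traffic, inositol_phospholipid, oxidative_stress, hsf1_chaperones, general_stress, ribosomal_protein, ribosome_biogenesis, translation_factors, amino_acid_gcn4, sulfur_met4, iron_aft1, zinc_zap1, copper, phosphate_pho, vatpase, proteasome, respiration_tca, glycolysis, pentose_phosphate, ergosterol, cell_wall_integrity, multidrug_pdr, mata_cell_markers, matalpha_cell_markers, haploid_pheromone, sporulation_diploid, strain_markers and histones_s_phase. With the estimated correlation, only translation factors, histones and α-cell markers held for the mean change. In single strains the calls that held were translation factors, vacuolar ATPase, α-cell markers and histones on the arrays labelled vma13Δ, translation factors, α-cell markers and histones in sse2Δ, and chaperones, translation factors and α-cell markers in skn7Δ. No call held in WT, in yap1Δ, untreated or in the differences from WT.

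The gene lists, the comparisons, the alternative settings and the rule for naming genes were set before the data were examined. The rule named the 4 deleted genes, the 10 highest and 10 lowest called genes of the mean DTT change with the same sign in all strains, up to 5 highest and 5 lowest called genes of each other comparison, 7 ER genes (KAR2, PDI1, ERO1, EUG1, LHS1, HAC1 and INO1) and the members of a described list with the largest change. Within a strain or between 2 groups, every array of one group had to lie on the same side of every array of the other. Genes with only a systematic name, a probe with no gene name and the strain's own deleted gene were passed over as extremes. Not every gene the rule selected is printed. List members printed without a p-value were called. The percentile was first taken over unflagged spots. The fixed definition, over all non-control spots, was settled after the first counts were seen. The reason was 1134 flagged spots on vma13Δ untreated array 1 (0 to 60 elsewhere). The first version stays as an added alternative.

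A fold is given as "at least" where a called gene was well above background on no array of one side, or was saturated on all arrays of one side and none of the other. Genes saturated on only some arrays carry no bound. For deleted genes and YIL092W, values under the lowest signal well above background were raised to it. The alternative settings were quantile normalization, normexp background correction with an offset of 50, the deposited value table, no filter, a filter of 10 arrays, the mean of all probes, the slide as a fixed or random block (consensus correlation -0.0209), a replicate block, the mutants only, only the groups compared, the other mutants as reference, and leaving out each array. The slide came from the file headers: 8, 7 and 4 arrays on slides 1, 2 and 3, with slide 3 scanned on another day.

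The model was tested on 6167 simulated genes, with 200 changed. It recovered 96 % of changes of 2 log2 units and 74 % of 1 in the mean DTT comparison (180 called, 10 of them unchanged), 67 % and 7 % for sse2Δ DTT (77 and 3), 45 % and 7 % for WT DTT (56 and 4), 71 % and 17 % for untreated sse2Δ (89 and 1) and 20 % and 1 % for the sse2Δ difference from WT (21 and 0). Recovery on arrays of unequal spread may differ. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.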

Results

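Gene expression was measured on 19 one-colour Cy3 Agilent arrays of Saccharomyces cerevisiae, untreated or given 5 mM dithiothreitol (DTT), a reducing agent that disturbs disulfide bond formation in the endoplasmic reticulum (ER). The labels named a wild-type (WT) reporter strain and the deletion strains vma13Δ, sse2Δ, yap1Δ and skn7Δ. Each strain had 2 untreated and 2 DTT arrays, except that WT had 1 DTT array. The description of untreated yap1Δ array 2 alone names 6 h of growth, and background strain labels differ between samples, with 1 background assumed. Nothing in the files said that replicates came from separate cultures, so the p-values measured only the spread between these samples, and the number of arrays limited the precision. Values are log2 changes ± standard error from a limma model with 6167 genes tested, with adjusted p-values from limma for genes and from camera for gene lists.

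SSE2, YAP1 and SKN7 signal was almost absent on the arrays labelled with their deletion. SSE2 averaged -9.10 ± 1.36 (SD) on its 4 arrays against -1.18 ± 1.68 on the other 15, at least 151-fold lower (adjusted p = 4.86e-07). YAP1 averaged -8.88 ± 1.03 against 0.95 ± 0.69, at least 502-fold lower (adjusted p = 3.00e-09), and SKN7 -8.07 ± 2.01 against -2.24 ± 0.41, at least 39.3-fold lower (adjusted p = 1.60e-04). On the arrays labelled vma13Δ the VMA13 transcript was present at 2.03 ± 0.41 (n = 4) against 2.22 ± 0.49 (n = 15), a change of -0.17 ± 0.17 (adjusted p = 0.603), and all 4 values were well above background. The gene lost on those 4 arrays was YIL092W, chosen after values were seen, at -9.46 ± 0.97 with 0 of 4 above background against -2.80 ± 0.40, at least 42.5-fold lower (adjusted p = 3.48e-09). YIL092W lies on chromosome IX and VMA13 on chromosome XVI. Each direction given for the arrays labelled vma13Δ therefore belongs to the label and not to a shown loss of VMA13.

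**Figure D1:**
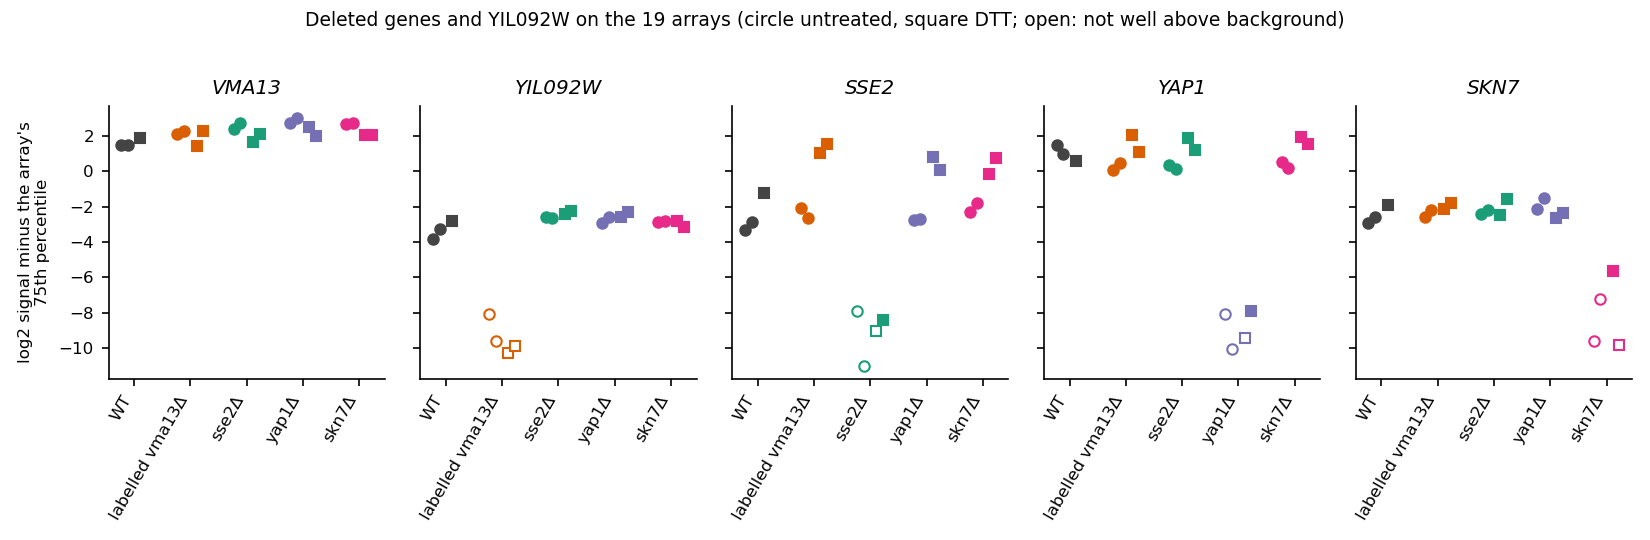
Level of VMA13, YIL092W, SSE2, YAP1 and SKN7 on each of the 19 arrays, in log2 of signal scaled to the array's 75th percentile, by strain label (circle untreated, square DTT, open where not well above background). VMA13 on the arrays labelled vma13Δ averaged 2.03 against 2.22 elsewhere, while YIL092W averaged -9.46 against -2.80.

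Averaged over the 5 strains, DTT lowered transcripts of the translation machinery, the division cycle and mating. Ribosomal protein genes fell (134 of 136 lower, 134 adjusted over the list alone, median -2.81, adjusted p = 6.97e-40, adjusted p = 0.114 with an estimated correlation). Among the deepest were RPL8A (-4.12 ± 0.28, adjusted p = 7.35e-08) and RPL24A (-4.03 ± 0.21, adjusted p = 1.48e-08). Ribosome biogenesis genes fell (66 of 67 lower, 66 adjusted over the list alone, median -1.69, adjusted p = 1.69e-20, adjusted p = 0.24 with an estimated correlation). DBP2 (-2.88 ± 0.36) and RPA135 (-2.80 ± 0.18) had the largest changes. Translation factors fell (35 of 42 lower and 1 higher, 37 and 1 adjusted over the list alone, median -1.16, adjusted p = 8.44e-11, adjusted p = 0.0234 with an estimated correlation). HYP2 (-2.69 ± 0.14) and NIP1 (-2.08 ± 0.18) had the largest changes. Histone and cell-cycle genes fell (18 of 19 lower and 1 higher, 18 and 1 adjusted over the list alone, median -1.97, adjusted p = 4.26e-09, adjusted p = 0.0332 with an estimated correlation). CLB6 (-3.19 ± 0.21), CLB1 (-3.16 ± 0.17) and HTB2 (-3.03 ± 0.20) moved furthest. The 4 α-cell marker genes fell (4 of 4 lower, 4 adjusted over the list alone, median -4.45, adjusted p = 1.92e-04, adjusted p = 0.0332 with an estimated correlation). MF(ALPHA)2 (-5.67 ± 0.29, adjusted p = 1.24e-08), MF(ALPHA)1 (-4.55 ± 0.18, adjusted p = 2.70e-09), SAG1 (-4.36 ± 0.24, adjusted p = 2.01e-08) and STE3 (-2.93 ± 0.18) stood at the extreme. Pheromone-pathway genes fell (10 of 15 lower and 1 higher, 11 and 2 adjusted over the list alone, median -0.81, adjusted p = 0.00258, adjusted p = 0.197 with an estimated correlation). FAR1 (-3.54 ± 0.21) and FIG1 (-2.46 ± 0.34) had the largest changes. Gcn4 amino acid genes fell (34 of 50 lower and 4 higher, 34 and 4 adjusted over the list alone, median -0.85, adjusted p = 1.50e-07, adjusted p = 0.36 with an estimated correlation). LYS9 (-3.65 ± 0.16) and LEU9 (-3.23 ± 0.17) had the largest changes. Also among the 10 lowest were PHO3 (-5.00 ± 0.29, adjusted p = 2.54e-08), DSE2 (-4.95 ± 0.19, adjusted p = 2.70e-09), INA1 (-4.06 ± 0.27, adjusted p = 6.39e-08) and HXT4 (-4.04 ± 0.31, adjusted p = 2.05e-07).

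Chaperone, general stress, iron and oxidative stress genes rose. Heat-shock factor chaperones rose (22 of 26 higher, 22 adjusted over the list alone, median 1.95, adjusted p = 1.04e-07, adjusted p = 0.0732 with an estimated correlation). HSP26 (4.33 ± 0.30, adjusted p = 9.34e-08), SSA4 (3.13 ± 0.21) and HSP78 (3.08 ± 0.20) had the largest changes. General stress genes rose (22 of 30 higher and 2 lower, 22 and 2 adjusted over the list alone, median 1.39, adjusted p = 2.69e-04, adjusted p = 0.396 with an estimated correlation). HSP12 (5.10 ± 0.48, adjusted p = 1.24e-06) and TKL2 (2.53 ± 0.26) had the largest changes. Iron-regulon genes rose (19 of 28 higher and 3 lower, 19 and 3 adjusted over the list alone, median 1.18, adjusted p = 5.10e-04, adjusted p = 0.378 with an estimated correlation). TIS11 (2.96 ± 0.25) and ARN2 (2.68 ± 0.15) moved furthest. Oxidative stress genes rose (18 of 33 higher and 2 lower, 18 and 2 adjusted over the list alone, median 0.59, adjusted p = 0.0138, adjusted p = 0.465 with an estimated correlation). HBN1 (3.34 ± 0.27) and OYE3 (2.90 ± 0.45) stood at the extreme. Sulfur genes rose (16 of 30 higher and 5 lower, 16 and 5 adjusted over the list alone, median 0.50, adjusted p = 0.0478, adjusted p = 0.462 with an estimated correlation), with MET2 (2.58 ± 0.23) and STR3 (2.22 ± 0.24), although with the slide as a fixed block the list gave adjusted p = 0.0736. Also among the 10 highest were RTA1 (4.70 ± 0.18, adjusted p = 2.70e-09), HXT5 (4.68 ± 0.30, adjusted p = 5.49e-08), CPP3 (4.53 ± 0.40, adjusted p = 6.46e-07) and SPG4 (4.37 ± 0.49, adjusted p = 5.79e-06). The others were OSW2 (4.37 ± 0.18, adjusted p = 3.54e-09), RRT1 (4.29 ± 0.17, adjusted p = 2.70e-09), AMS1 (4.17 ± 0.18, adjusted p = 3.54e-09) and ROQ1 (4.11 ± 0.27, adjusted p = 6.95e-08).

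ER folding genes rose as a list (10 of 17 higher and 1 lower, 10 and 1 adjusted over the list alone, median 0.68, adjusted p = 0.044, adjusted p = 0.378 with an estimated correlation). Glycosylation and translocation genes fell (16 of 32 lower and 3 higher, 16 and 3 adjusted over the list alone, median -0.44, adjusted p = 0.00605, adjusted p = 0.378 with an estimated correlation). The oxidoreductin gene rose most, ERO1 (2.61 ± 0.14, adjusted p = 1.58e-08), followed by JEM1 (1.45 ± 0.17) and MPD1 (1.40 ± 0.20). The ER Hsp70 gene KAR2 (1.01 ± 0.17, adjusted p = 2.19e-04, saturated) rose too, as did LHS1 (0.72 ± 0.29, adjusted p = 0.0428), HAC1 (1.1 ± 0.30, adjusted p = 0.00641) and INO1 (2.19 ± 0.23, adjusted p = 3.71e-06). PDI1 (0.04 ± 0.16, adjusted p = 0.843) and EUG1 (0.23 ± 0.21, adjusted p = 0.352) were not called. Under quantile normalization PDI1 became called at 0.50 (adjusted p = 0.00646). Without the WT arrays the ER folding list gave adjusted p = 0.0661. The largest glycosylation changes were PMT4 (-2.24 ± 0.12) and PSA1 (-1.71 ± 0.16). The deleted genes, with the deletion arrays included, gave VMA13 (-0.38, adjusted p = 0.0342), SSE2 (2.35, adjusted p = 5.31e-05), YAP1 (0.75, adjusted p = 0.0332) and SKN7 (0.32, adjusted p = 0.574), and VMA13 under quantile normalization gave -0.03 (adjusted p = 0.884).

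Lipid, energy and vacuolar ATPase genes fell. Ergosterol genes (18 of 25 lower and 2 higher, 19 and 2 adjusted over the list alone, median -0.79, adjusted p = 1.12e-04, adjusted p = 0.24 with an estimated correlation) included ERG11 (-1.85 ± 0.19) and ERG1 (-1.83 ± 0.19). Vacuolar ATPase genes (12 of 17 lower and 1 higher, 12 and 1 adjusted over the list alone, median -0.68, adjusted p = 0.00138, adjusted p = 0.0732 with an estimated correlation) included VMA3 (-1.52 ± 0.16) and VMA2 (-1.38 ± 0.21). Respiration and citrate cycle genes (21 of 46 lower and 4 higher, 21 and 4 adjusted over the list alone, median -0.41, adjusted p = 0.00183, adjusted p = 0.378 with an estimated correlation) included COX4 (-2.33 ± 0.18) and CYC1 (-2.11 ± 0.28). Glycolysis genes (7 of 19 lower, 5 adjusted over the list alone, median -0.50, adjusted p = 0.0138, adjusted p = 0.378 with an estimated correlation) included PFK2 (-1.28 ± 0.15) and PFK1 (-1.09 ± 0.14), and quantile normalization removed that call (median -0.11, adjusted p = 0.413). Pentose phosphate genes (5 of 10 lower and 2 higher, 6 and 2 adjusted over the list alone, median -0.66, adjusted p = 0.0462, adjusted p = 0.378 with an estimated correlation) included RKI1 (-3.22 ± 0.23) and TKL1 (-1.50 ± 0.14), and quantile normalization removed that call too (adjusted p = 0.129).

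The remaining lists were not called for the mean DTT change. They were ER-associated degradation (10 of 17 higher and 2 lower, 10 and 2 adjusted over the list alone, median 0.44, adjusted p = 0.0917) and proteasome genes (12 of 36 higher and 2 lower, 8 and 2 adjusted over the list alone, median 0.26, adjusted p = 0.121). Others were zinc (10 of 18 lower and 5 higher, 10 and 6 adjusted over the list alone, median -0.45, adjusted p = 0.128) and phosphate genes (7 of 19 lower and 6 higher, 7 and 6 adjusted over the list alone, median -0.18, adjusted p = 0.509). Copper genes (2 of 11 higher and 3 lower, 2 and 1 adjusted over the list alone, median -0.01, mean 0.17, test direction up, adjusted p = 0.772) and ER to Golgi traffic (6 of 28 lower and 3 higher, 5 and 3 adjusted over the list alone, median -0.07, adjusted p = 0.509) had called members in both directions. So had inositol and phospholipid genes (9 of 17 lower and 7 higher, 9 and 7 adjusted over the list alone, median -0.33, mean 0.01, test direction down, adjusted p = 0.53). Cell wall genes (12 of 24 lower and 8 higher, 12 and 9 adjusted over the list alone, median -0.37, adjusted p = 0.48) were not called either. Nor were drug resistance genes (6 of 13 higher and 2 lower, 5 and 2 adjusted over the list alone, median 0.36, adjusted p = 0.713) and a-cell markers (4 of 6 higher, 4 adjusted over the list alone, median 1.21, adjusted p = 0.095). The last were sporulation genes (6 of 11 higher and 1 lower, 6 and 1 adjusted over the list alone, median 0.83, adjusted p = 0.0944) and strain marker genes (4 of 7 lower and 2 higher, 4 and 2 adjusted over the list alone, median -0.57, adjusted p = 0.153).

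**Figure D2:**
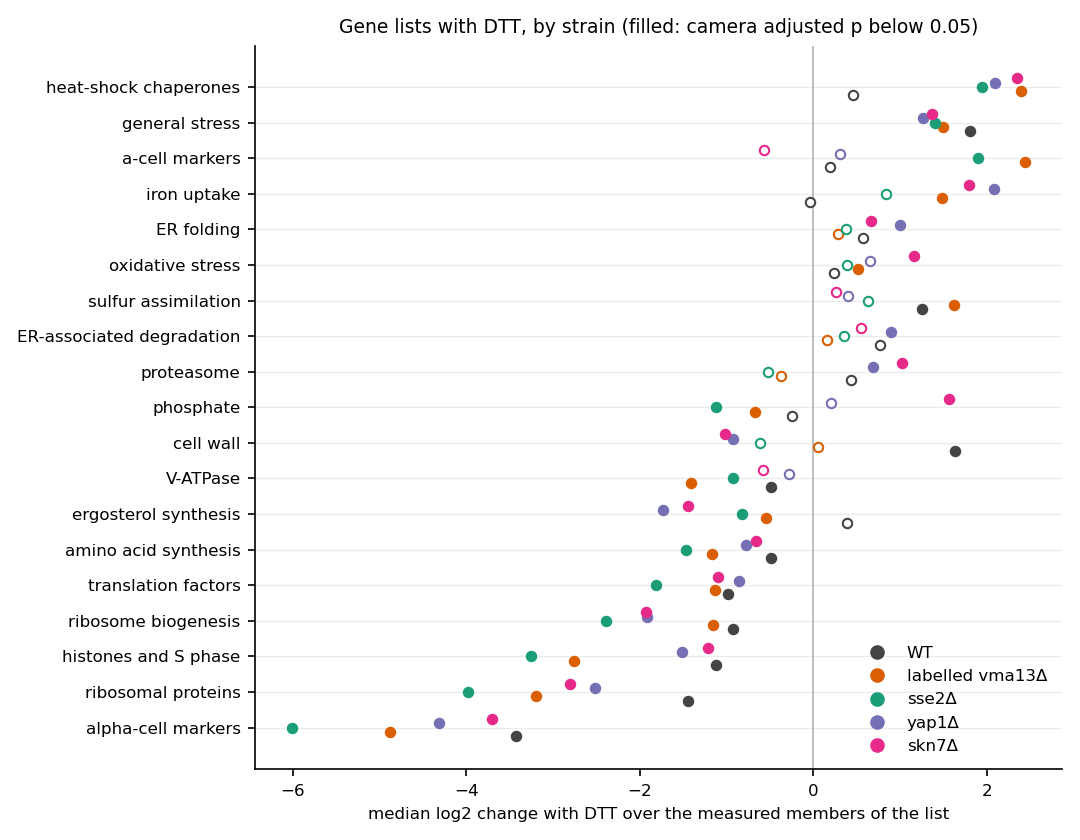
Median log2 DTT change of 19 gene lists in each of the 5 strains, filled where camera gave adjusted p below 0.05. Ribosomal protein genes lay at -1.44 in WT and -3.98 in sse2Δ, and cell wall genes at 1.63 in WT and -1.02 in skn7Δ.

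In the mean over strains 2222 genes were higher and 1721 lower with DTT, and 4123 had unadjusted p below 0.05. The median over all genes moved by 0.12, the level to set list medians against. At least 1 log2 unit was reached by 1014 higher and 931 lower genes. The slide block gave 2217 higher and 1708 lower, slide 1 alone 1666 and 1208 (vma13Δ label, sse2Δ and yap1Δ only), and slide 2 alone 1035 and 1122 (sse2Δ and yap1Δ only). Without the arrays labelled vma13Δ 4 lists lost their call: glycosylation (adjusted p = 0.0534), sulfur (0.145), glycolysis (0.0778) and pentose phosphate genes (0.0535). Within slide 1 or 2, 132 of 132 list medians and 189 of 195 named genes kept their sign, a weak test, since all-array values include both slides.

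On the 1 WT array given DTT, against 2 untreated, general stress, cell wall and sulfur genes were higher and ribosomal protein genes lower, with the spread taken from the other groups. General stress genes were higher (15 of 30 higher, 16 adjusted over the list alone, median 1.80, adjusted p = 4.42e-05, adjusted p = 0.723 with an estimated correlation). HSP12 (5.87 ± 1.25, adjusted p = 0.00854) and XBP1 (3.64 ± 0.75) had the largest changes. Cell wall genes were higher (11 of 24 higher and 1 lower, 14 and 1 adjusted over the list alone, median 1.63, adjusted p = 7.56e-05, adjusted p = 0.559 with an estimated correlation). PIR3 (4.51 ± 0.67) and NCW2 (4.24 ± 0.73, at least 18.9-fold, saturated) had the largest changes. Sulfur genes were higher (12 of 30 higher, 16 adjusted over the list alone, median 1.25, adjusted p = 1.65e-04, adjusted p = 0.434 with an estimated correlation). MET2 (2.64 ± 0.60) and MET28 (2.34 ± 0.64) had the largest changes. Ribosomal protein genes were lower (43 of 136 lower and 0 higher, 66 and 1 adjusted over the list alone, median -1.44, adjusted p = 3.48e-24, adjusted p = 0.378 with an estimated correlation). The α-cell markers were lower (4 of 4 lower, 4 adjusted over the list alone, median -3.42, adjusted p = 4.42e-05, adjusted p = 0.0531 with an estimated correlation). SAG1 (-4.89 ± 0.63, adjusted p = 4.98e-04) and MF(ALPHA)2 (-4.35 ± 0.76, adjusted p = 0.003) stood at the extreme. The highest single genes were RTA1 (6.76 ± 0.48, adjusted p = 2.05e-05), SPG4 (6.27 ± 1.28, adjusted p = 0.00684), CPP3 (6.12 ± 1.04, adjusted p = 0.00262) and LDS2 (5.99 ± 0.62, adjusted p = 1.70e-04). CTS1 (-3.83 ± 0.49, adjusted p = 4.98e-04), DSE2 (-3.81 ± 0.49, adjusted p = 4.98e-04) and DSE4 (-3.68 ± 0.40, adjusted p = 2.13e-04) were among the lowest. INO1 (2.95 ± 0.61, adjusted p = 0.00733) was higher. Of the other ER genes, KAR2 (0.56 ± 0.45, adjusted p = 0.425, saturated), PDI1 (0.98 ± 0.41, adjusted p = 0.12, saturated) and ERO1 (1.05 ± 0.36, adjusted p = 0.0646) were not called. EUG1 (-0.13 ± 0.55, adjusted p = 0.892), LHS1 (-0.71 ± 0.75, adjusted p = 0.549) and HAC1 (-0.17 ± 0.79, adjusted p = 0.902) were not called either. Under quantile normalization KAR2 at 1.24 (adjusted p = 0.0147), PDI1 at 1.48 (adjusted p = 0.0183) and ERO1 at 1.43 (adjusted p = 0.0108) were called. The deleted genes gave VMA13 (0.41, adjusted p = 0.48), SSE2 (1.86, adjusted p = 0.169), YAP1 (-0.65, adjusted p = 0.57) and SKN7 (0.84, adjusted p = 0.67). In all 669 genes were higher and 414 lower (1985 at unadjusted p below 0.05), with a median over all genes of 0.11. The slide block left 310 higher and 174 lower, the DTT array lying on another slide than both controls.

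On the arrays labelled vma13Δ (2 against 2), DTT raised sulfur, chaperone and a-cell genes and lowered vacuolar ATPase and histone genes. Sulfur genes rose (16 of 30 higher and 2 lower, 16 and 2 adjusted over the list alone, median 1.62, adjusted p = 1.36e-04, adjusted p = 0.238 with an estimated correlation). MET2 (4.79 ± 0.49) and STR3 (4.40 ± 0.50) had the largest changes. Chaperones rose (19 of 27 higher and 1 lower, 20 and 1 adjusted over the list alone, median 2.40, adjusted p = 2.93e-07, adjusted p = 0.0886 with an estimated correlation). Genes marking a cells rose (4 of 6 higher, 4 adjusted over the list alone, median 2.44, adjusted p = 0.00913, adjusted p = 0.204 with an estimated correlation). STE2 (3.76 ± 0.31), ASG7 (3.29 ± 0.72) and STE6 (2.50 ± 0.33) had the largest changes. The α-cell markers fell (4 of 4 lower, 4 adjusted over the list alone, median -4.88, adjusted p = 1.55e-05, adjusted p = 0.0154 with an estimated correlation). MF(ALPHA)2 (-6.24 ± 0.62, adjusted p = 1.65e-05) and MF(ALPHA)1 (-5.27 ± 0.37, adjusted p = 3.17e-06) had the largest changes. Vacuolar ATPase genes fell (11 of 17 lower, 11 adjusted over the list alone, median -1.41, adjusted p = 3.68e-05, adjusted p = 0.0203 with an estimated correlation). VMA3 (-2.89 ± 0.41, 1 untreated vma13Δ array) and VMA11 (-2.31 ± 0.33) had the largest changes. Histone and cycle genes fell (18 of 19 lower and 0 higher, 18 and 1 adjusted over the list alone, median -2.76, adjusted p = 7.42e-12, adjusted p = 0.0154 with an estimated correlation). Ribosomal protein genes fell (119 of 136 lower, 128 adjusted over the list alone, median -3.20, adjusted p = 2.23e-44, adjusted p = 0.0886 with an estimated correlation). RPL21A (-5.76 ± 0.68, adjusted p = 5.05e-05) and RPL8A (-4.98 ± 0.59) moved furthest. Translation factors fell (24 of 42 lower and 1 higher, 27 and 1 adjusted over the list alone, median -1.14, adjusted p = 1.30e-09, adjusted p = 0.0154 with an estimated correlation). ERO1 (2.71 ± 0.30, adjusted p = 3.10e-05, at least 6.55-fold, saturated) and INO1 (2.69 ± 0.50, adjusted p = 0.00119) rose. PDI1 (-1.03 ± 0.34, adjusted p = 0.029) fell, but lay at -0.20 under quantile normalization (adjusted p = 0.628). KAR2 (0.54 ± 0.37, adjusted p = 0.277, saturated), EUG1 (-0.35 ± 0.45, adjusted p = 0.569), LHS1 (-0.51 ± 0.61, adjusted p = 0.544) and HAC1 (0.91 ± 0.65, adjusted p = 0.292) were not called. Under quantile normalization KAR2 was called (adjusted p = 6.67e-04). The other extremes were SRX1 (6.08 ± 1.07, adjusted p = 8.15e-04), BSC5 (5.68 ± 0.68, adjusted p = 5.14e-05), HXT5 (5.47 ± 0.64, adjusted p = 4.95e-05), HSP30 (5.45 ± 1.25, adjusted p = 0.00516, 1 untreated vma13Δ array) and LIN1 (5.32 ± 0.57, adjusted p = 2.60e-05) upward. Downward they were LEU2 (-5.27 ± 0.31, adjusted p = 2.68e-06) and HXT6 (-5.06 ± 0.97, adjusted p = 0.00148). The deleted genes gave VMA13 (-0.35, adjusted p = 0.4), SSE2 (3.61, adjusted p = 0.00201), YAP1 (1.33, adjusted p = 0.0982) and SKN7 (0.45, adjusted p = 0.754). In all 1372 genes were higher and 931 lower (2883 at unadjusted p below 0.05), the median over all genes was 0.16, quantile normalization gave 1186 and 1194, the percentile over unflagged spots 1139 and 1118, the slide block 1300 and 867, and slide 1 alone gave 1004 and 732.

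In sse2Δ (2 against 2) DTT lowered translation, histone and α-cell genes. Ribosomal protein genes fell (128 of 136 lower, 130 adjusted over the list alone, median -3.98, adjusted p = 3.02e-41, adjusted p = 0.106 with an estimated correlation). RPL8A (-6.08 ± 0.59, adjusted p = 7.41e-06) and RPP1B (-5.81 ± 0.43) had the largest changes. Translation factors fell (31 of 42 lower and 1 higher, 33 and 1 adjusted over the list alone, median -1.81, adjusted p = 1.78e-10, adjusted p = 0.0212 with an estimated correlation). Histone and cycle genes fell (18 of 19 lower, 18 adjusted over the list alone, median -3.26, adjusted p = 1.19e-10, adjusted p = 0.0212 with an estimated correlation). The α-cell markers fell (4 of 4 lower, 4 adjusted over the list alone, median -6.01, adjusted p = 9.41e-05, adjusted p = 0.0261 with an estimated correlation), with MF(ALPHA)2 (-7.77 ± 0.62, adjusted p = 2.27e-06), MF(ALPHA)1 (-7.52 ± 0.37, adjusted p = 2.15e-07) and STE3 (-4.49 ± 0.38), and LEU2 (-6.07 ± 0.31, adjusted p = 2.15e-07) fell beside them. Genes marking a cells rose (3 of 6 higher, 4 adjusted over the list alone, median 1.90, adjusted p = 0.0149, adjusted p = 0.25 with an estimated correlation). ASG7 (4.69 ± 0.72), STE2 (3.93 ± 0.31) and STE6 (2.69 ± 0.33) had the largest changes. Chaperones rose (18 of 26 higher and 1 lower, 19 and 1 adjusted over the list alone, median 1.95, adjusted p = 1.17e-06, adjusted p = 0.106 with an estimated correlation). Glycosylation genes fell (18 of 32 lower and 2 higher, 20 and 2 adjusted over the list alone, median -0.95, adjusted p = 8.26e-05, adjusted p = 0.25 with an estimated correlation). ERO1 (2.89 ± 0.30, adjusted p = 1.09e-05, at least 7.42-fold, saturated), HAC1 (2.35 ± 0.65, adjusted p = 0.0101) and INO1 (2.78 ± 0.50, adjusted p = 7.16e-04) rose. PDI1 (-1.32 ± 0.34, adjusted p = 0.00669) fell. KAR2 (0.60 ± 0.37, adjusted p = 0.2, saturated), EUG1 (0.17 ± 0.45, adjusted p = 0.777) and LHS1 (0.99 ± 0.61, adjusted p = 0.202) were not called. Under quantile normalization KAR2 was called (adjusted p = 0.00389). The other extremes were SPG4 (6.63 ± 1.05, adjusted p = 2.78e-04), REC104 (6.15 ± 0.42, adjusted p = 1.01e-06) and SHC1 (5.63 ± 0.43, adjusted p = 1.90e-06). Next were CPP3 (5.43 ± 0.85, adjusted p = 2.49e-04), LIN1 (5.30 ± 0.57, adjusted p = 1.46e-05) and DSE2 (-5.98 ± 0.40, adjusted p = 1.00e-06). The deleted genes gave VMA13 (-0.71, adjusted p = 0.0751), SSE2 (0.73, adjusted p = 0.431, not above background), YAP1 (1.27, adjusted p = 0.0981) and SKN7 (0.30, adjusted p = 0.826). In all 1473 genes were higher and 1413 lower (3357 at unadjusted p below 0.05). The slide block gave 1483 and 1409, slide 1 alone 988 and 846, and slide 2 alone 641 and 926.

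In yap1Δ (2 arrays against 2) iron, ER folding and chaperone genes rose and ergosterol and cell wall genes fell. Iron genes rose (19 of 28 higher and 0 lower, 19 and 1 adjusted over the list alone, median 2.08, adjusted p = 2.83e-08, adjusted p = 0.166 with an estimated correlation). FIT2 (6.91 ± 0.58, adjusted p = 9.98e-06) and FIT3 (5.50 ± 0.41, adjusted p = 5.11e-06) had the largest changes. ER folding genes rose (10 of 17 higher, 13 adjusted over the list alone, median 0.99, adjusted p = 6.36e-05, adjusted p = 0.148 with an estimated correlation). ERO1 (3.07 ± 0.30, adjusted p = 2.07e-05), MPD1 (2.61 ± 0.44) and JEM1 (2.59 ± 0.37) had the largest changes. ER-associated degradation genes rose (7 of 17 higher, 8 adjusted over the list alone, median 0.89, adjusted p = 0.0126, adjusted p = 0.174 with an estimated correlation). KAR2 (1.22 ± 0.37, adjusted p = 0.0206, at least 2.33-fold, saturated), LHS1 (2.12 ± 0.61, adjusted p = 0.0164), HAC1 (1.76 ± 0.65, adjusted p = 0.0481) and INO1 (1.78 ± 0.50, adjusted p = 0.0139) rose. PDI1 (0.83 ± 0.34, adjusted p = 0.0691, saturated) and EUG1 (0.92 ± 0.45, adjusted p = 0.129) were not called. Under quantile normalization PDI1 was called at 1.11 (adjusted p = 0.0101), and HAC1 lost its call with the slide block (adjusted p = 0.0544). Chaperones rose (19 of 27 higher, 20 adjusted over the list alone, median 2.09, adjusted p = 1.69e-09, adjusted p = 0.0705 with an estimated correlation). BTN2 (5.66 ± 0.43, adjusted p = 6.06e-06) and SSA4 (4.21 ± 0.46) had the largest changes. Ergosterol genes fell (18 of 25 lower and 1 higher, 18 and 1 adjusted over the list alone, median -1.73, adjusted p = 1.79e-07, adjusted p = 0.137 with an estimated correlation). ERG5 (-4.23 ± 0.51) and ERG11 (-4.05 ± 0.40) fell most. Cell wall genes fell (11 of 24 lower and 3 higher, 12 and 4 adjusted over the list alone, median -0.93, adjusted p = 0.00662, adjusted p = 0.401 with an estimated correlation). PIR1 (-5.64 ± 0.66, adjusted p = 6.65e-05) and CWP2 (-5.44 ± 0.68, at least 43.4-fold, saturated) moved furthest. Ribosomal protein genes fell (106 of 136 lower and 0 higher, 114 and 1 adjusted over the list alone, median -2.52, adjusted p = 2.54e-31, adjusted p = 0.148 with an estimated correlation). The other extremes were CAN1 (5.49 ± 0.75, adjusted p = 2.21e-04) and RRT1 (5.38 ± 0.36, adjusted p = 4.84e-06) upward. Downward, PHO3 (-6.84 ± 0.62, adjusted p = 1.31e-05), AAH1 (-6.14 ± 0.82, adjusted p = 1.38e-04), DSE2 (-5.66 ± 0.40, adjusted p = 5.11e-06) and MF(ALPHA)2 (-5.59 ± 0.62, adjusted p = 4.49e-05) were the others. The deleted genes gave VMA13 (-0.61, adjusted p = 0.145), SSE2 (3.19, adjusted p = 0.00439), YAP1 (0.39, adjusted p = 0.656, not above background) and SKN7 (-0.70, adjusted p = 0.632). In all 1213 genes were higher and 1042 lower (2807 at unadjusted p below 0.05). The slide block gave 1216 and 1045, slide 1 alone 359 and 366, and slide 2 alone 454 and 566. Leaving out 1 yap1Δ array gave 1327 to 1560 in all, and only the groups compared 3485.

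In skn7Δ (2 arrays against 2) chaperone, proteasome, oxidative stress and phosphate genes rose. Chaperones rose (24 of 27 higher, 24 adjusted over the list alone, median 2.35, adjusted p = 5.28e-13, adjusted p = 0.0406 with an estimated correlation). HSP26 (5.92 ± 0.64, adjusted p = 7.25e-05) and SSA4 (4.70 ± 0.46) moved furthest. Proteasome genes rose (20 of 36 higher, 26 adjusted over the list alone, median 1.02, adjusted p = 2.04e-07, adjusted p = 0.123 with an estimated correlation). Oxidative stress genes rose (15 of 33 higher and 2 lower, 16 and 2 adjusted over the list alone, median 1.16, adjusted p = 2.18e-04, adjusted p = 0.338 with an estimated correlation). HBN1 (5.94 ± 0.58, adjusted p = 4.14e-05) and OYE3 (5.44 ± 0.92, adjusted p = 0.00101) stood at the extreme. Phosphate genes rose (11 of 19 higher, 11 adjusted over the list alone, median 1.56, adjusted p = 0.00327, adjusted p = 0.275 with an estimated correlation). PHO84 (4.23 ± 0.96) and SPL2 (4.20 ± 0.74) had the largest changes. ER folding genes rose (7 of 17 higher, 7 adjusted over the list alone, median 0.67, adjusted p = 0.00139, adjusted p = 0.225 with an estimated correlation). ERO1 (3.32 ± 0.30, adjusted p = 3.57e-05) and KAR2 (2.13 ± 0.37, adjusted p = 9.40e-04, at least 4.39-fold, saturated) had the largest changes. LHS1 (1.69 ± 0.61, adjusted p = 0.0484) rose. PDI1 (0.73 ± 0.34, adjusted p = 0.115), EUG1 (0.55 ± 0.45, adjusted p = 0.377), HAC1 (0.67 ± 0.65, adjusted p = 0.468) and INO1 (0.77 ± 0.50, adjusted p = 0.264) were not called. PDI1 under quantile normalization was called at 0.89 (adjusted p = 0.0322), and LHS1 in the deposited value table was not (adjusted p = 0.0537). Translation factors fell (24 of 42 lower and 1 higher, 28 and 1 adjusted over the list alone, median -1.09, adjusted p = 5.08e-08, adjusted p = 0.0406 with an estimated correlation). Ribosomal protein genes fell (119 of 136 lower, 124 adjusted over the list alone, median -2.81, adjusted p = 8.41e-38, adjusted p = 0.123 with an estimated correlation). The other extremes were ECM4 (5.4 ± 0.52, adjusted p = 4.14e-05) and HSP12 (5.39 ± 1.02, adjusted p = 0.00165) upward. The lowest were AAH1 (-5.29 ± 0.82, adjusted p = 4.87e-04), PHO3 (-5.11 ± 0.62, adjusted p = 1.12e-04), DBP2 (-5.01 ± 0.77, adjusted p = 4.79e-04), DSE2 (-4.45 ± 0.40, adjusted p = 3.57e-05) and MF(ALPHA)2 (-4.40 ± 0.62, adjusted p = 2.63e-04). The deleted genes gave VMA13 (-0.65, adjusted p = 0.123), SSE2 (2.37, adjusted p = 0.0233), YAP1 (1.39, adjusted p = 0.0914) and SKN7 (0.70, adjusted p = 0.642, not above background). In all 1119 genes were higher and 987 lower (2696 at unadjusted p below 0.05), and slide 3, which held only the skn7Δ arrays, gave 1026 and 910 alone. Leaving out 1 skn7Δ array gave 1090 to 1731 in all.

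**Figure D3:**
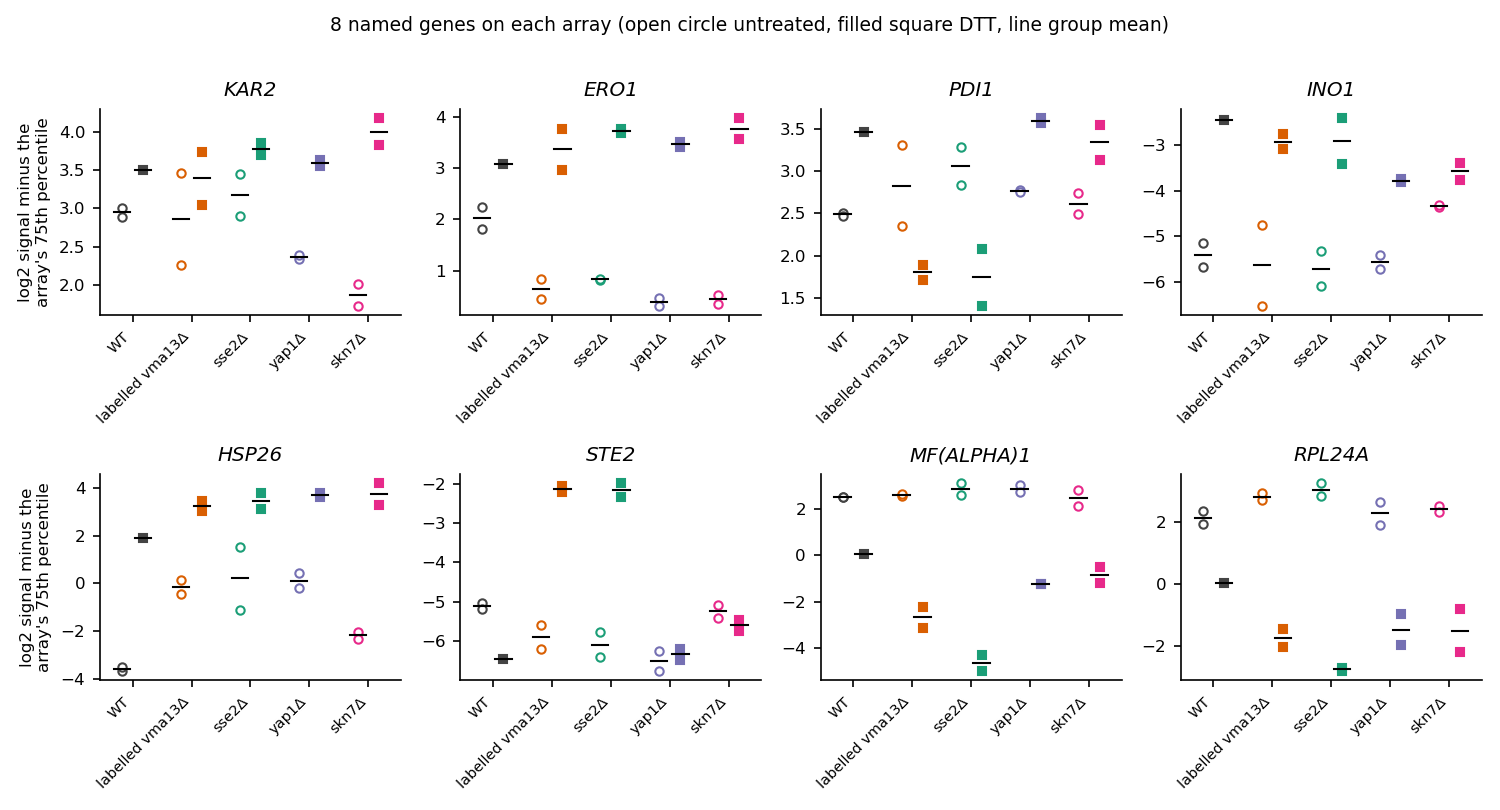
Level of KAR2, ERO1, PDI1, INO1, HSP26, STE2, MF(ALPHA)1 and RPL24A on each array, in log2 of scaled signal, untreated and DTT by strain, with a line at each group mean. The STE2 change with DTT was 3.93 in sse2Δ and -1.34 in WT.

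The DTT change in each deletion strain minus that in WT was tested with the same 1 WT DTT array and the same assumption on its spread. On the arrays labelled vma13Δ, chaperones responded more than in WT (9 of 27 higher and 0 lower, 12 and 1 adjusted over the list alone, median 1.34, adjusted p = 7.15e-06, adjusted p = 0.23 with an estimated correlation). CUR1 (5.86 ± 0.50, adjusted p = 1.91e-04) and BTN2 (4.19 ± 0.68) had the largest changes. The response of a-cell markers was higher too (2 of 6 higher, 2 adjusted over the list alone, median 1.72, adjusted p = 0.00783, adjusted p = 0.23 with an estimated correlation). STE2 (5.10 ± 0.49) and ASG7 (2.48 ± 1.14, adjusted p = 0.177) had the largest values. Ribosomal protein genes responded lower (39 of 136 lower, 51 adjusted over the list alone, median -1.48, adjusted p = 3.82e-14, adjusted p = 0.413 with an estimated correlation). Respiration genes responded lower (10 of 46 lower, 17 adjusted over the list alone, median -1.38, adjusted p = 5.28e-07, adjusted p = 0.23 with an estimated correlation). Cell wall genes responded lower (3 of 24 lower, 6 adjusted over the list alone, median -1.37, adjusted p = 1.74e-04, adjusted p = 0.413 with an estimated correlation). LSC2 (-4.04 ± 0.67) and PST1 (-3.84 ± 0.73) were among the largest changes. HSP30 (7.80 ± 1.77, adjusted p = 0.0198, 1 untreated vma13Δ array), SRX1 (6.45 ± 1.69, adjusted p = 0.0315), GPX2 (6.04 ± 1.54, adjusted p = 0.0289), NRG1 (6.03 ± 0.67, adjusted p = 0.00131, saturated, 1 untreated vma13Δ array) and ERO1 (1.66 ± 0.47, adjusted p = 0.0409, saturated) responded more than in WT. TDH1 (-5.52 ± 1.08, adjusted p = 0.0103), BNA2 (-4.82 ± 0.75, adjusted p = 0.00374), RPL21A (-4.50 ± 1.08, adjusted p = 0.0226), CLN2 (-4.45 ± 0.72, adjusted p = 0.00455), TOS6 (-4.45 ± 1.02, adjusted p = 0.0191) and PDI1 (-2.01 ± 0.53, adjusted p = 0.033, saturated) responded less. With the slide block HSP30 (adjusted p = 0.0523), GPX2 (0.0758), TDH1 (0.0648), RPL21A (0.14), TOS6 (0.0763), PDI1 (0.0858) and ERO1 (0.189) lost their calls. KAR2 (-0.02, adjusted p = 0.988, saturated), EUG1 (-0.22, adjusted p = 0.877), LHS1 (0.20, adjusted p = 0.922), HAC1 (1.08, adjusted p = 0.54) and INO1 (-0.26, adjusted p = 0.867) were not called. Nor were the deleted genes VMA13 (-0.76, adjusted p = 0.346), SSE2 (1.75, adjusted p = 0.355), YAP1 (1.99, adjusted p = 0.193) and SKN7 (-0.39, adjusted p = 0.905). In all 333 genes were higher and 322 lower (1708 at unadjusted p below 0.05). The split was 280 and 446 with the percentile taken over unflagged spots, and 79 and 40 with the slide block.

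In sse2Δ the response of chaperones exceeded that of WT (11 of 26 higher and 1 lower, 11 and 1 adjusted over the list alone, median 0.93, adjusted p = 3.67e-05, adjusted p = 0.391 with an estimated correlation). CUR1 (5.52 ± 0.50, adjusted p = 1.44e-04) and MDJ1 (4.54 ± 0.40) had the largest changes. The response of a-cell markers was higher too (3 of 6 higher, 3 adjusted over the list alone, median 1.64, adjusted p = 0.0138, adjusted p = 0.391 with an estimated correlation). STE2 (5.27 ± 0.49, adjusted p = 1.44e-04) and ASG7 (3.88 ± 1.14) moved furthest. Ribosomal protein genes responded lower (77 of 136 lower, 87 adjusted over the list alone, median -2.41, adjusted p = 1.46e-17, adjusted p = 0.391 with an estimated correlation). Cell wall genes responded lower (12 of 24 lower, 12 adjusted over the list alone, median -2.06, adjusted p = 3.67e-05, adjusted p = 0.391 with an estimated correlation). Histone genes responded lower (12 of 19 lower and 0 higher, 13 and 1 adjusted over the list alone, median -2.26, adjusted p = 1.27e-04, adjusted p = 0.391 with an estimated correlation). CLN2 (-4.79 ± 0.72) and PST1 (-6.50 ± 0.73, adjusted p = 3.88e-04) stood at the extreme. NRG1 (6.26 ± 0.61, adjusted p = 3.33e-04, saturated), REC104 (5.76 ± 0.67, adjusted p = 5.51e-04), AEP3 (5.53 ± 0.52, adjusted p = 1.44e-04) and ERO1 (1.84 ± 0.47, adjusted p = 0.0163, saturated) responded more. THI13 (-5.89 ± 0.80, adjusted p = 0.00125, not above background), TOS6 (-5.79 ± 1.02, adjusted p = 0.00328), THI11 (-5.64 ± 1.09, adjusted p = 0.0049), THI12 (-5.25 ± 0.64, adjusted p = 6.80e-04) and PDI1 (-2.29 ± 0.53, adjusted p = 0.0105, saturated) responded less. KAR2 (0.05, adjusted p = 0.962, saturated), EUG1 (0.30, adjusted p = 0.79), LHS1 (1.70, adjusted p = 0.22), HAC1 (2.52, adjusted p = 0.0926) and INO1 (-0.17, adjusted p = 0.898) were not called. Nor were the deleted genes VMA13 (-1.12, adjusted p = 0.114), SSE2 (-1.13, adjusted p = 0.503, not above background), YAP1 (1.93, adjusted p = 0.157) and SKN7 (-0.54, adjusted p = 0.834). In all 594 genes were higher and 797 lower (2302 at unadjusted p below 0.05), the median over all genes was -0.19, and the slide block left 358 and 451.

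In yap1Δ the response of iron genes exceeded that of WT (11 of 28 higher and 1 lower, 16 and 1 adjusted over the list alone, median 2.10, adjusted p = 2.15e-10, adjusted p = 0.215 with an estimated correlation). FIT2 (6.69 ± 0.91, adjusted p = 0.00219) and FIT3 (4.65 ± 0.65) had the largest changes. Chaperones were higher (8 of 27 higher, 11 adjusted over the list alone, median 1.31, adjusted p = 4.23e-09, adjusted p = 0.139 with an estimated correlation). ER folding genes were higher (1 of 17 higher, 1 adjusted over the list alone, median 0.67, adjusted p = 0.00868, adjusted p = 0.435 with an estimated correlation). BTN2 (6.70 ± 0.68, adjusted p = 3.23e-04), CUR1 (5.00 ± 0.50) and MPD1 (2.04 ± 0.69, adjusted p = 0.102) had the largest values. Cell wall genes were lower (12 of 24 lower, 19 adjusted over the list alone, median -2.68, adjusted p = 7.10e-12, adjusted p = 0.21 with an estimated correlation). Ergosterol genes were lower (12 of 25 lower, 16 adjusted over the list alone, median -1.91, adjusted p = 2.74e-10, adjusted p = 0.139 with an estimated correlation). Sulfur genes were lower (3 of 30 lower, 3 adjusted over the list alone, median -0.98, adjusted p = 0.00209, adjusted p = 0.435 with an estimated correlation). NFG1 (-6.26 ± 1.07, adjusted p = 0.00723), CWP2 (-5.84 ± 1.08, adjusted p = 0.01, saturated), MET6 (-6.76 ± 0.67, adjusted p = 3.04e-04) and ERG11 (-4.02 ± 0.64) had the largest changes. Further single genes were HSP30 (6.93 ± 1.61, adjusted p = 0.0288, saturated), PDR12 (5.97 ± 0.49, adjusted p = 1.21e-04), YRO2 (5.77 ± 1.56, adjusted p = 0.0469) and ERO1 (2.01 ± 0.47, adjusted p = 0.0269) upward. Downward there were TOS6 (-6.64 ± 1.02, adjusted p = 0.00393) and SVS1 (-6.48 ± 0.79, adjusted p = 0.00142). YRO2 (adjusted p = 0.0921) and ERO1 (0.0762) lost their calls with the slide block. KAR2 (0.67, adjusted p = 0.549, saturated), PDI1 (-0.14, adjusted p = 0.905, saturated), EUG1 (1.05, adjusted p = 0.419), LHS1 (2.83, adjusted p = 0.107), HAC1 (1.94, adjusted p = 0.292) and INO1 (-1.17, adjusted p = 0.42) were not called. Nor were the deleted genes VMA13 (-1.02, adjusted p = 0.244), SSE2 (1.33, adjusted p = 0.543), YAP1 (1.04, adjusted p = 0.565, not above background) and SKN7 (-1.54, adjusted p = 0.622). In all 140 genes were higher and 230 lower (1351 at unadjusted p below 0.05), and the slide block left 71 and 118.

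In skn7Δ the response of chaperones exceeded that of WT (10 of 27 higher, 17 adjusted over the list alone, median 1.63, adjusted p = 6.30e-13, adjusted p = 0.0737 with an estimated correlation). BTN2 (5.04 ± 0.68, adjusted p = 0.0041) and FES1 (4.27 ± 0.46) had the largest changes. Phosphate genes were higher (1 of 19 higher and 1 lower, 6 and 1 adjusted over the list alone, median 1.52, adjusted p = 2.39e-05, adjusted p = 0.251 with an estimated correlation). Oxidative stress genes were higher (2 of 33 higher, 6 adjusted over the list alone, median 0.74, adjusted p = 0.00132, adjusted p = 0.613 with an estimated correlation). SPL2 (6.49 ± 1.17, adjusted p = 0.00984), PHO84 (5.67 ± 1.51, adjusted p = 0.053) and OYE3 (4.65 ± 1.46, adjusted p = 0.0882) had the largest values. Cell wall genes were lower (9 of 24 lower, 19 adjusted over the list alone, median -2.76, adjusted p = 1.01e-11, adjusted p = 0.229 with an estimated correlation). Ergosterol genes were lower (9 of 25 lower, 13 adjusted over the list alone, median -1.55, adjusted p = 1.74e-08, adjusted p = 0.229 with an estimated correlation). PIR3 (-5.50 ± 0.87, adjusted p = 0.00757), YPS3 (-5.27 ± 0.60, adjusted p = 0.00146), NFG1 (-5.09 ± 1.07, adjusted p = 0.0213) and ERG10 (-3.81 ± 0.64) stood at the extreme. Further single genes were CUP1-1 (5.21 ± 1.13, adjusted p = 0.0238, saturated), CUP1-2 (5.20 ± 1.1, adjusted p = 0.0214, saturated), NCE102 (4.75 ± 0.85, adjusted p = 0.00984) and ERO1 (2.27 ± 0.47, adjusted p = 0.0201) upward. Lower responses were those of LDS2 (-5.61 ± 0.81, adjusted p = 0.00607) and DBP2 (-4.97 ± 1.22, adjusted p = 0.0394). With the slide block CUP1-1 (adjusted p = 0.0651), CUP1-2 (0.0608), NFG1 (0.0594), DBP2 (0.107) and ERO1 (0.0579) lost their calls. KAR2 (1.58, adjusted p = 0.134, saturated), PDI1 (-0.25, adjusted p = 0.82, saturated), EUG1 (0.68, adjusted p = 0.62), LHS1 (2.40, adjusted p = 0.167), HAC1 (0.84, adjusted p = 0.678) and INO1 (-2.18, adjusted p = 0.125) were not called. Nor were the deleted genes VMA13 (-1.06, adjusted p = 0.221), SSE2 (0.51, adjusted p = 0.831), YAP1 (2.05, adjusted p = 0.224) and SKN7 (-0.14, adjusted p = 0.972, not above background). In all 127 genes were higher and 149 lower (1378 at unadjusted p below 0.05), and the slide block left 57 and 62.

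Before treatment, transcripts of the mitochondrial genome differed between arrays, also within groups. The mean level of 21 mitochondrially encoded genes was -2.75 ± 0.02 (SD) on the 2 WT untreated arrays, -4.13 ± 2.18 on those labelled vma13Δ, -5.13 ± 2.02 in sse2Δ, -5.52 ± 0.23 in yap1Δ and -6.52 ± 1.11 in skn7Δ. All 4 untreated comparisons share those 2 WT arrays.

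**Figure D4:**
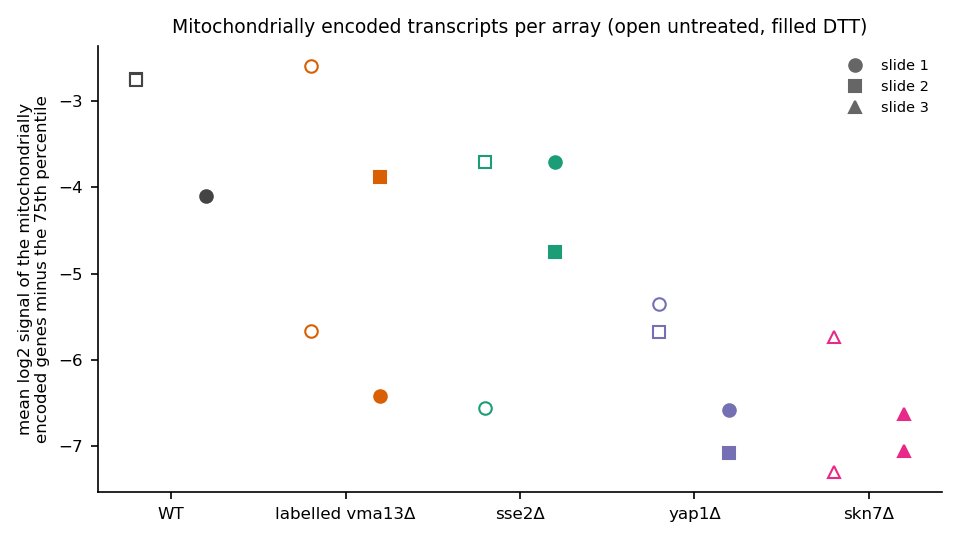
Mean level of 21 mitochondrially encoded genes on each array, in log2 of scaled signal, by group with the marker showing the slide. WT untreated arrays lay at -2.74 and -2.76, yap1Δ untreated at a mean of -5.52.

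Untreated arrays labelled vma13Δ (2 against 2) had more chaperone and respiration transcripts than WT and less of ribosome biogenesis. Chaperones were higher (5 of 27 higher and 1 lower, 11 and 1 adjusted over the list alone, median 0.90, adjusted p = 0.00562, adjusted p = 0.759 with an estimated correlation). Respiration genes were higher (8 of 46 higher, 20 adjusted over the list alone, median 0.97, adjusted p = 5.46e-04, adjusted p = 0.759 with an estimated correlation). HSP26 (3.42 ± 0.64, adjusted p = 0.0259), SSA4 (3.08 ± 0.46, adjusted p = 0.0228), ACO1 (2.0 ± 0.43) and LSC2 (1.97 ± 0.42) had the largest changes. Ribosome biogenesis genes were lower (12 of 67 lower, 20 adjusted over the list alone, median -0.74, adjusted p = 1.42e-10, adjusted p = 0.759 with an estimated correlation). NOP7 (-2.56 ± 0.65, adjusted p = 0.0461, 1 untreated vma13Δ array) and EBP2 (-2.50 ± 0.41, adjusted p = 0.0254) had the largest changes. Ribosomal protein genes (1 of 136 lower, 0 adjusted over the list alone, median -0.34, adjusted p = 0.0285, adjusted p = 0.912 with an estimated correlation) were lower, with RPL23B (-2.34 ± 0.98, adjusted p = 0.142, 1 untreated vma13Δ array) not called, but at a median of 0.00 under quantile normalization. Translation factors (6 of 42 lower and 0 higher, 6 and 2 adjusted over the list alone, median -0.21, adjusted p = 0.0394, adjusted p = 0.759 with an estimated correlation) were lower with SUP35 (-1.98 ± 0.28), but at 0.225 under quantile normalization. Single genes were ARO10 (3.20 ± 0.66, adjusted p = 0.03), GCV1 (2.99 ± 0.60, adjusted p = 0.0293) and OPT2 (2.89 ± 0.49, adjusted p = 0.0254) upward. URM1 (-3.04 ± 0.81, adjusted p = 0.0473), NOP53 (-2.73 ± 0.55, adjusted p = 0.0294) and SPB1 (-2.53 ± 0.56, adjusted p = 0.0355) were lower. The deleted genes VMA13 (0.74, adjusted p = 0.137), SSE2 (0.75, adjusted p = 0.505), YAP1 (-0.96, adjusted p = 0.296) and SKN7 (0.36, adjusted p = 0.843) were not called. In all 164 genes were higher and 166 lower (1802 at unadjusted p below 0.05), with a median over all genes of 0.15. The split was 494 and 149 with the percentile over unflagged spots and 264 and 162 in the deposited value table. The slide block left 1 higher and 1 lower, and of the single genes named only SSA4 kept its call. The mitochondrial covariate left 92, and without WT untreated array 1 there was 1.

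In untreated sse2Δ (2 against 2) chaperones were higher than in WT (8 of 26 higher and 0 lower, 16 and 2 adjusted over the list alone, median 1.11, adjusted p = 2.27e-04, adjusted p = 0.839 with an estimated correlation). Gcn4 genes were higher as well (9 of 50 higher and 0 lower, 16 and 1 adjusted over the list alone, median 0.88, adjusted p = 2.27e-04, adjusted p = 0.839 with an estimated correlation). HSP26 (3.79 ± 0.64, adjusted p = 0.0262), SSA4 (3.50 ± 0.46, adjusted p = 0.0121), ARG1 (1.99 ± 0.56) and THR4 (1.96 ± 0.38) had the largest changes. Further genes were DAK2 (2.98 ± 0.69, adjusted p = 0.0319, at least 4.11-fold, not above background) and ARO10 (2.52 ± 0.66, adjusted p = 0.042) upward. MIX14 (-3.66 ± 0.80, adjusted p = 0.031), EFG1 (-3.52 ± 0.99, adjusted p = 0.0489), ATX1 (-3.43 ± 0.86, adjusted p = 0.0388), NOP53 (-3.37 ± 0.55, adjusted p = 0.0262) and TIM11 (-3.27 ± 0.88, adjusted p = 0.0473) were lower. The deleted gene was lower, SSE2 (-6.38 ± 0.73, adjusted p = 0.00557, at least 46.6-fold, not above background), beside VMA13 (1.1, adjusted p = 0.0484), YAP1 (-0.94, adjusted p = 0.271) and SKN7 (0.45, adjusted p = 0.77). In all 238 genes were higher and 235 lower (2114 at unadjusted p below 0.05), the median over all genes was 0.31, and quantile normalization gave 64 and 151. The slide block left 1 higher and 3 lower, with HSP26 at 4.08 (adjusted p = 0.0512), and slide 2 alone gave 23 and 6. The covariate left 3, and without WT untreated array 1 there were 0.

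In untreated yap1Δ (2 against 2) Gcn4 genes were higher than in WT (23 of 50 higher and 0 lower, 29 and 1 adjusted over the list alone, median 1.07, adjusted p = 1.62e-06, adjusted p = 0.907 with an estimated correlation). General stress genes were higher too (14 of 30 higher, 15 adjusted over the list alone, median 1.34, adjusted p = 5.73e-04, adjusted p = 0.913 with an estimated correlation). ARG1 (3.29 ± 0.56, adjusted p = 0.00636), HIS4 (2.59 ± 0.34) and SOL4 (2.29 ± 0.73) had the largest changes. Ribosomal protein genes were lower (15 of 136 lower, 6 adjusted over the list alone, median -0.81, adjusted p = 3.82e-06, adjusted p = 0.913 with an estimated correlation), with RPL23B (-3.18 ± 0.80) and RPL41B (-3.06 ± 0.77), but not under quantile normalization (median -0.06, adjusted p = 0.263). Single genes were GCV2 (4.36 ± 0.52, adjusted p = 0.004), HSP26 (3.70 ± 0.64, adjusted p = 0.00647), GCV1 (3.49 ± 0.60, adjusted p = 0.00636) and ARO10 (3.19 ± 0.66, adjusted p = 0.009) upward. GPX2 (-5.70 ± 0.97, adjusted p = 0.00635) and RPC17 (-4.66 ± 0.96, adjusted p = 0.009) were lower. The mitochondrially encoded COX3 (-5.00 ± 1.41, adjusted p = 0.0222), VAR1 (-4.67 ± 1.56, adjusted p = 0.0409, at least 17.2-fold, not above background) and COX1 (-4.57 ± 1.60, adjusted p = 0.0471) were lower. YAP1 (-10.27 ± 0.60, adjusted p = 2.05e-06, at least 576-fold, not above background) was lower, beside VMA13 (1.39, adjusted p = 0.0109), SSE2 (0.34, adjusted p = 0.748) and SKN7 (0.94, adjusted p = 0.495). In all 987 genes were higher and 847 lower (2760 at unadjusted p below 0.05), with a median over all genes of 0.18. The slide block left 526 and 529, and slide 2 alone gave 299 and 515. The covariate left 19, and without WT untreated array 1 there were 30.

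In untreated skn7Δ (2 against 2) general stress genes were higher than in WT (10 of 30 higher and 1 lower, 13 and 1 adjusted over the list alone, median 1.1, adjusted p = 0.0234, adjusted p = 0.919 with an estimated correlation). Sulfur genes were higher too (9 of 30 higher, 11 adjusted over the list alone, median 0.91, adjusted p = 0.035, adjusted p = 0.919 with an estimated correlation). SOL4 (2.20 ± 0.73), MET2 (2.24 ± 0.49) and SAM2 (1.84 ± 0.60) moved furthest. Ribosomal protein genes (8 of 136 lower, 2 adjusted over the list alone, median -0.47, adjusted p = 0.00263, adjusted p = 0.919 with an estimated correlation) were lower with RPL23B (-2.92 ± 0.80) and RPS22B (-2.72 ± 0.57), but at a median of 0.05 under quantile normalization and 0.16 with the mitochondrial covariate. Single genes were HUG1 (4.62 ± 0.63, adjusted p = 0.00822), DAN1 (3.94 ± 0.77, adjusted p = 0.0104, at least 12.6-fold, not above background), RNR3 (3.26 ± 0.38, adjusted p = 0.00717), GTT2 (3.25 ± 0.45, adjusted p = 0.00822) and YPS5 (2.98 ± 0.79, adjusted p = 0.0231, at least 5.56-fold, not above background) upward. The mitochondrially encoded ATP8 (-6.54 ± 1.44, adjusted p = 0.0148), COX1 (-6.44 ± 1.60, adjusted p = 0.019), COB (-6.32 ± 1.44, adjusted p = 0.0156), ATP6 (-6.05 ± 1.23, adjusted p = 0.0124) and AI5_ALPHA (-5.73 ± 1.23, adjusted p = 0.0148) were lower. SKN7 (-5.66 ± 1.01, adjusted p = 0.00881, at least 33.7-fold, not above background) was lower, beside VMA13 (1.22, adjusted p = 0.0196), SSE2 (1.03, adjusted p = 0.29) and YAP1 (-0.86, adjusted p = 0.284). In all 892 genes were higher and 710 lower (2605 at unadjusted p below 0.05), with a median over all genes of 0.26, and quantile normalization gave 501 and 551. The covariate left 0, and without WT untreated array 1 there were 0. All skn7Δ arrays lay on slide 3 with no WT array, so slide and strain cannot be told apart there.

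Taking the other mutants as reference left few untreated genes. Only YIL092W (-6.09 ± 0.34, adjusted p = 1.04e-06) was called for the arrays labelled vma13Δ and only SSE2 (-7.08 ± 0.59, adjusted p = 1.62e-04) for sse2Δ. In yap1Δ 45 were called, with COS12 (-4.22 ± 0.48, adjusted p = 0.00265) lower and GCV2 (2.85 ± 0.42, adjusted p = 0.0146) higher. In skn7Δ 21 were called, with ARO10 (-4.31 ± 0.54, adjusted p = 0.00814) lower and HUG1 (3.48 ± 0.52, adjusted p = 0.0106) higher.

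Across genes the DTT changes of the strains correlated, with genes taken as points and not as independent replicates. The arrays labelled vma13Δ went with sse2Δ (r = 0.871) and yap1Δ with skn7Δ (r = 0.889). Between those pairs r was 0.663 (vma13Δ label with yap1Δ), 0.652 (vma13Δ label with skn7Δ), 0.620 (sse2Δ with yap1Δ) and 0.612 (sse2Δ with skn7Δ). WT gave 0.483 with the vma13Δ label, 0.346 with sse2Δ, 0.515 with yap1Δ and 0.516 with skn7Δ. The 10 correlations were not tested against each other. Between single DTT arrays, array 1 of the vma13Δ label had r = 0.987 and 0.97 with the sse2Δ arrays but 0.919 with its replicate, while array 2 was at 0.918 and 0.932 with them and at 0.908 to 0.931 with those of yap1Δ and skn7Δ.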

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

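The differences from WT, the reassignment of DTT labels, the slide block and the other mutants as reference were planned. The use of the last 2 to weigh explanations, and the tests on the VMA13 label, the mating genes and an RNA batch, were chosen after the results were seen. Each gene passed limma's interaction test for DTT against WT, without the slide block. It assumes an equal spread for the 1 WT DTT array, but replicate differences had an SD of 0.375 to 1.029 by group, so p-values are uncertain. On the arrays labelled vma13Δ 655 genes differed: HSP30 7.80, SRX1 6.45, GPX2 6.04, NRG1 6.03, CUR1 5.86, ERO1 1.66, TDH1 -5.52, BNA2 -4.82, RPL21A -4.50, CLN2 -4.45, TOS6 -4.45 and PDI1 -2.01. In sse2Δ 1391 differed: NRG1 6.26, REC104 5.76, AEP3 5.53, CUR1 5.52, STE2 5.27, ERO1 1.84, PST1 -6.50, THI13 -5.89, TOS6 -5.79, THI11 -5.64, THI12 -5.25 and PDI1 -2.29. In yap1Δ 370 differed: HSP30 6.93, BTN2 6.70, FIT2 6.69, PDR12 5.97, YRO2 5.77, ERO1 2.01, MET6 -6.76, TOS6 -6.64, SVS1 -6.48, NFG1 -6.26 and CWP2 -5.84. In skn7Δ 276 differed: SPL2 6.49, CUP1-1 5.21, CUP1-2 5.20, BTN2 5.04, NCE102 4.75, ERO1 2.27, LDS2 -5.61, PIR3 -5.50, YPS3 -5.27, NFG1 -5.09 and DBP2 -4.97. All rest on the same 1 DTT and 2 untreated WT arrays. Untreated ERO1 was 2.02 in WT, 0.39 to 0.83 elsewhere. The slide block left 119, 809, 189 and 119 genes, and 7, 0, 2 and 5 listed genes lost calls. Values are not exact for THI13, not above background in 2 groups, or, with saturated groups, for NRG1, PDI1 and ERO1 (vma13Δ label and sse2Δ), HSP30 and CWP2 (yap1Δ) and CUP1-1 and CUP1-2.

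For the mean DTT change, only the real one of 100 splits of DTT labels within strains gave 3943 genes. The others gave at most 1811. Chance between cultures was not tested.

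The VMA13 transcript was present on the arrays labelled vma13Δ. A swap with another strain of the series needs VMA13 to be lost elsewhere, and the lowest value among the other 15 arrays was 1.45, which argues against it. Another strain hybridised under this label needs a different gene to be lost on all 4 arrays, and 1 gene was, YIL092W. A strain lacking YIL092W is therefore a candidate explanation, not shown from the strain itself. No biological explanation was tested.

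STE2, STE6 and ASG7 rose with DTT in sse2Δ and on the arrays labelled vma13Δ. MATa cells would bring MFA1 and MFA2 (mean change in sse2Δ 0.44 against 3.93 for STE2), but both lay near background and cannot decide. With the mitochondrial covariate STE2 stayed at 3.93, but an RNA or labelling batch need not follow that covariate. No biological explanation was tested.

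Untreated mutants differed from WT in many genes at once. In yap1Δ slide is not the whole cause, since 1045 of 1834 calls kept call and direction with the slide block. On the arrays labelled vma13Δ 2 of 330 calls were kept and in sse2Δ 4 of 473. All kept their sign, and their median change went from 1.46 (median standard error 0.33) to 1.25 (0.38) and from 1.42 (0.34) to 1.33 (0.34), so calls near the threshold ended and slide stays open. In skn7Δ slide and strain cannot be told apart. Against the other 3 mutants yap1Δ left 45 genes (1, 1 and 21 for the others), but counts are not effect sizes. An RNA or labelling batch fits in part. Of 7 replicate differences sharing no array with WT minus yap1Δ, that of DTT under the vma13Δ label correlated with it across genes at r = 0.793, untreated sse2Δ and vma13Δ label at 0.51 and 0.335, DTT in sse2Δ, yap1Δ and skn7Δ at 0.218, -0.268 and -0.032, and untreated skn7Δ at -0.13. Effects of the single deletions, a response shared by all and growth state stay open.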

How the results depend on the processing

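The covariate, unflagged-spot percentile, quality weights, fold limit, arrays labelled vma13Δ left out and the array with most flagged spots left out were chosen after seeing the data. Of the gene counts 202 stayed within 1.5 times the main count and 88 moved. Of named genes 3647 kept direction and call, 263 lost the call, 54 gained one and 9 reversed; of lists 2407, 99, 5 and 21. A change of sign with neither value called counts as kept. The mean DTT change stayed between 3656 and 4113 genes except for 1945 at 1 log2 unit or more. Here vma13Δ means the arrays labelled so. Unless named, the cause was not tested.

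Quantile normalization moved untreated vma13Δ to 4 genes, sse2Δ to 215 and skn7Δ to 1052, and reversed 3 list medians: ribosomal proteins in untreated vma13Δ (0.002) and skn7Δ (0.05) and translation factors in untreated vma13Δ (0.225). It shifted the median over all genes from 0.11 to -0.02 for WT DTT, 0.16 to 0.00 for vma13Δ DTT and 0.31 to 0.13 for untreated sse2Δ. Normexp moved untreated sse2Δ to 241 genes. The slide block gave 484 for WT DTT, 2, 4 and 1055 for untreated vma13Δ, sse2Δ and yap1Δ, and 119, 809, 189 and 119 for the differences from WT of vma13Δ, sse2Δ, yap1Δ and skn7Δ. It could not be fitted for untreated skn7Δ, whose slide holds no other strain.

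Using only the groups compared, with fewer arrays behind the spread, gave 757, 1915 and 3485 for DTT in vma13Δ, sse2Δ and yap1Δ, 0, 0, 3193 and 2715 for the 4 untreated comparisons, and 0, 1452 and 503 for the differences of vma13Δ, yap1Δ and skn7Δ. Where limma called 0, unadjusted p was below 0.05 for 1287 genes in untreated vma13Δ, 1899 in untreated sse2Δ and 941 in the vma13Δ difference.

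The other mutants as reference gave 1, 1, 45 and 21 untreated. The differences had 7, 512, 258 and 146, of which 4, 342, 57 and 22 were main calls. Reversed values there were, untreated: NOP53 0.557, ribosomal proteins 0.061 and Gcn4 genes -0.381 in vma13Δ, EFG1 0.42, TIM11 0.213 and VMA13 -0.016 in sse2Δ, YAP1 3.198 and Gcn4 genes -0.104 in skn7Δ. In the differences they were CLN2 0.223, TOS6 0.934, ERO1 -0.382, chaperones -0.25, iron -0.492, ergosterol 0.9 and cell wall 0.851 in vma13Δ, and ERO1 -0.14, chaperones -0.283, respiration 0.104, ergosterol 0.156 and cell wall 0.241 in sse2Δ. In yap1Δ they were chaperones -0.094, ribosomal proteins 0.797 and pentose phosphate 0.217, and in skn7Δ ribosomal proteins 0.529, respiration 0.515 and pentose phosphate 0.177. The reference itself differs, and for YAP1 holds the yap1Δ arrays.

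The mitochondrial covariate gave 92, 3, 19 and 0 untreated (669 at unadjusted p below 0.05 in skn7Δ) and 650 for the yap1Δ difference, and reversed ribosomal proteins in untreated skn7Δ (0.164). The unflagged-spot percentile gave 643 for untreated vma13Δ. Quality weights gave 1653, 768 and 3793 for DTT in WT, vma13Δ and yap1Δ, 1, 949, 3597 and 3106 untreated, and 206, 1235 and 925 for the differences of vma13Δ, yap1Δ and skn7Δ. Leaving out the array with most flagged spots gave 3 for untreated vma13Δ, 1001 for untreated sse2Δ and 482 for the skn7Δ difference.

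Leaving out single arrays gave 3666 to 4025 for the mean, 426 to 650 for WT, 1996 to 2196 for vma13Δ, 2214 to 2394 for sse2Δ, 1327 to 1560 for yap1Δ and 1090 to 1731 for skn7Δ. Untreated ranges were 1 to 643, 0 to 319, 1 to 577 and 0 to 277, and those of the differences 267 to 1302, 768 to 1343, 91 to 204 and 76 to 261. A lone array left in a group was assumed to vary like the other groups. Without WT untreated array 1 the counts fell to 426 for WT DTT, to 1 and 0 for untreated vma13Δ and sse2Δ (1076 and 1093 at unadjusted p below 0.05), to 0 for untreated skn7Δ (1633), and to 267 and 768 for the vma13Δ and sse2Δ differences. Without yap1Δ untreated array 2 untreated yap1Δ fell to 1, without yap1Δ DTT array 1 DTT in yap1Δ to 1327, without skn7Δ DTT array 2 DTT in skn7Δ to 1090, without yap1Δ untreated array 1 its difference to 91, and without skn7Δ untreated array 2 its difference to 76. Without vma13Δ DTT array 2 its difference rose to 1302.

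Replicate numbers did not pair the arrays: untreated and DTT replicate differences correlated across genes at 0.316, 0.084, -0.299 and -0.051. A replicate block over the 16 mutant arrays gave 3937 for the mean and 2213, 2804, 2186 and 2005 for the 4 strains. Results with WT were not fitted with that block. Signal limited dim and bright genes: 88.9 % to 97.7 % of spots were well above background and 59 to 531 spots per array were saturated, so called KAR2 changes are lower bounds for DTT in yap1Δ and skn7Δ.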

Other observations

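These genes and tests were chosen after values were seen. LEU2 fell with DTT beside the α-specific genes: -6.07 ± 0.31 in sse2Δ, -5.27 ± 0.31 on the arrays labelled vma13Δ, -3.33 ± 0.31 in skn7Δ, -2.90 ± 0.31 in yap1Δ and -1.57 ± 0.39 in WT. MATALPHA1 fell in sse2Δ (-1.77 ± 0.28), on the arrays labelled vma13Δ (-1.36 ± 0.35) and in WT (-1.14 ± 0.35) and was not called in yap1Δ and skn7Δ. MATALPHA2 rose in sse2Δ (1.5 ± 0.52), yap1Δ (1.51 ± 0.52) and skn7Δ (1.57 ± 0.52). Against the other mutants, PHO84 (7.22) and SPL2 (4.20) had a higher DTT response in skn7Δ, FIT2 (5.44) and FIT3 (3.46) in yap1Δ, and SAM3 (3.50) and MHT1 (3.48) on the arrays labelled vma13Δ.

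Differences between arrays varied with coding length, not in one direction. Between the 2 DTT arrays labelled vma13Δ the median was 0.78 in genes of up to 300 nucleotides, -0.43 at 800 to 1200 and -0.11 above 2000, and for untreated WT minus yap1Δ 0.68, -0.45 and -0.18.

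A hypothesis is that RNA state or labelling lies behind untreated differences from WT. The 7 correlations above (r = -0.268 to 0.793) are its basis, not its test. The 3 highest (0.793, 0.51 and 0.335) had the largest mitochondrial differences, in reverse order (2.55, 2.86 and 3.09).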
